A study of Rattus norvegicus with 8 samples.

How the data were processed

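Gene expression was measured on 8 Affymetrix whole-transcript arrays from fetal pancreatic islets of Sprague-Dawley rats. Per the labels, the dams had either surgery to restrict growth of the fetuses in the uterus (IUGR, intrauterine growth restriction) or a sham operation on embryonic day 18, and islets were collected on embryonic day 19. The islets of all fetuses of a litter were pooled, so that each array stands for 1 litter of 1 dam, with 4 sham litters and 4 IUGR litters. The replicate is therefore the litter. The labels name RNAzol B for RNA isolation and a biotin label. They name no sort or gate after islet isolation.

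The deposited values are log2 expression values, made with RMA per the submitters' processing notes (RMA corrects background, normalizes between arrays by quantiles and summarises probes). The distributions of the deposited values over the tested genes still differed between arrays. The version, software and probe filters are not given in the sources used here. The table held 29214 probe sets with a value on all 8 arrays. Genes were named through the platform annotation, with gene identifiers checked against RefSeq annotation of the rat assembly GRCr8. That annotation gave exactly 1 gene for 15310 probe sets, several for 323 and none for 13581. Of the 1-gene probe sets, 15279 matched a current gene identifier and 31 did not and kept the name in the annotation. Where 1 gene had several probe sets (527 genes), the one with the highest mean was used, leaving 14506 genes. No coordinates were used. Array data have no read depth, and the number of arrays limits the precision.

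The deposited log2 values were tested without further normalization in limma 3.58.1 under R 4.3.3 (lmFit and eBayes, 2 groups, no covariate). P-values were two-sided and adjusted over the 14506 genes by the method of Benjamini and Hochberg, with a threshold of 0.05. Standard errors are those of the moderated fit, with 8.21 total degrees of freedom. A set of 32 gene lists, with 814 genes measured of 943 entries, was tested with camera at a preset correlation of 0.01, again with camera and an estimated correlation, and with fry. Adjusted p-values of the lists were taken over the 32 lists. An exact two-sided permutation test of the list mean per array over 70 arrangements was added after the data were examined, and 0.0286 is the smallest p it can give. Single values were compared with the same exact test.

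The groups, the tests, the gene lists, the rule for named genes and most of the processing alternatives were set before the data were examined. The rule named the 12 higher and the 12 lower genes with the largest difference among those past the threshold and with no overlap between groups, filled up by smallest p where a direction had fewer than 12. It also named up to 4 members of each list by smallest p, and 16 genes of islet function, growth and cytokines whatever their values. Pdx1 and Mafa, which were among those 16, had no probe set with 1 gene and were not analysed here, and 1 other of them is not reported here. In all, 157 genes were named, and every one entered the comparison of processing alternatives.

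The alternatives were quantile normalization, median centring, a filter on the 30% dimmest genes, a trended robust prior, array weights, the replicate number as a block, the mean of a gene's probe sets, all probe sets, and leaving out each litter in turn. Cyclic loess, arrays left out together, the 5 arrays of wider signal range and list means as covariates were chosen after the data were examined. On data simulated from these 14506 genes, with 200 genes changed in each of 20 runs, the test recovered 72.5% of genes changed 2-fold and 93% of those changed 4-fold, and 5.78% of calls were unchanged genes. The simulated genes varied independently of one another, with no effect shared across an array. These shares therefore need not hold for the real arrays, where genes vary together. Figures were drawn with matplotlib 3.10.9.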

Results

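Fetal islets of 4 sham-operated and 4 IUGR litters were profiled 1 day after surgery, at embryonic day 19, with 1 array per litter. The median of the probe sets lay between 7.70 and 7.81 (log2) on the 8 arrays. Correlations between arrays, across genes, ranged from 0.924 to 0.992. The first principal component held 43.7% of the variance and the second 23.1%. The arrays differed in their signal range. The interquartile range of gene values was 3.53 to 3.62 in the IUGR litters and 3.63 in sham replicate 1, but 3.20, 3.23 and 3.06 in sham replicates 2, 3 and 4. The group means were 3.56 ± 0.04 and 3.28 ± 0.24 (SD, n = 4 each), with an exact permutation p of 0.143.

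**Figure D1:**
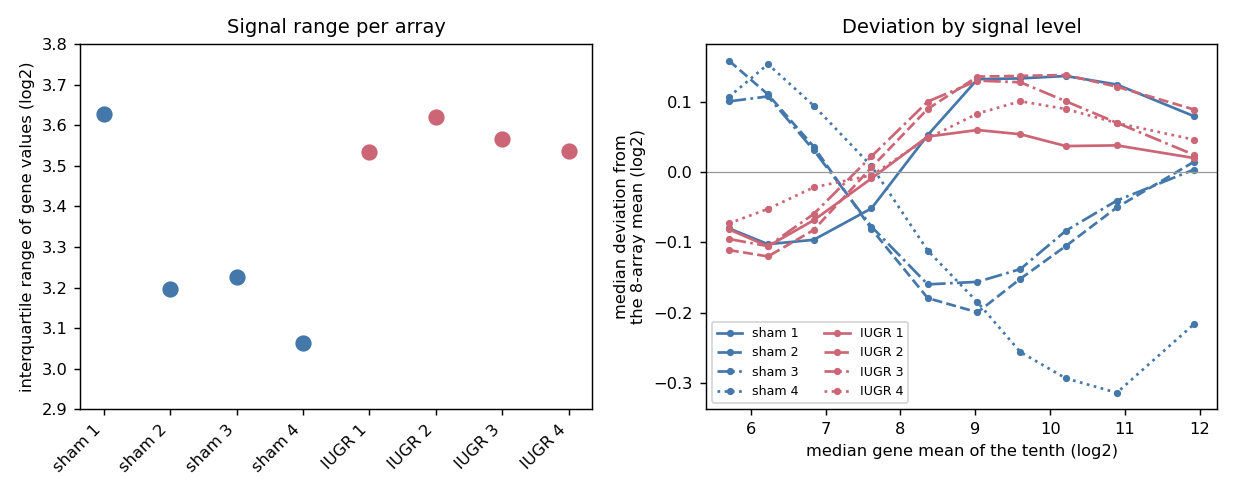
Left, interquartile range of gene values (log2) on each array; right, the median deviation of each array from the 8-array mean (log2) for groups of genes ordered by mean signal (x axis, log2), with sham arrays in blue and IUGR arrays in red. Sham replicate 1 had a range of 3.63, close to the IUGR arrays, and sham replicate 4 had the lowest range, 3.06.

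The comparison of IUGR with sham litters asked which islet genes differ 1 day after surgery. In IUGR islets, 36 of 14506 genes changed, 34 of them higher and 2 lower. The 34 were higher by a median of 1.19 on the log2 scale, from 0.69 to 2.39. Car12, a carbonic anhydrase, had the largest rise at 2.39 ± 0.34 (SE, n = 4 litters per group), from 8.73 to 11.12. Ndn, which encodes necdin, fell by 2.11 ± 0.23 (SE), from 12.38 to 10.27.

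Among the largest rises, the methyltransferase gene Gnmt rose by 2.12, Fam83b by 1.98, the splicing factor gene Esrp2 by 1.92, the desmosomal cadherin gene Dsc2 by 1.83 and the lipase gene Liph by 1.78. Rap1gap rose by 1.64, the transcription factor Hnf4a by 1.61, the potassium channel gene Kcnj13 by 1.61, Bex4 by 1.48, the small heat shock protein gene Hspb8 by 1.38 and Mgst2 by 1.35. Gimap7, a GTPase gene of lymphoid cells, fell by 0.88 ± 0.13 (SE) and was the only other lower gene past the threshold. Adjusted p-values of the 36 genes lay between 0.043 and 0.048 (limma), and in all 36 the 4 IUGR litters did not overlap the 4 sham litters. Over all genes, 15.5% showed no overlap, where chance gives 2.86%. The next lower genes did not pass: Cdkn1c, a cell cycle inhibitor, differed by -0.74 (adjusted p = 0.070), C1qtnf5 by -0.65, Cxcr6 by -0.69, Ccr1l1 by -0.65, Scart1 by -0.42, Apobr by -0.35, Cd27 by -0.49, Xcl1 by -0.48, Shisa4 by -0.52 and Phf11b by -0.67.

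The count of 36 was not stable. It was 0 after quantile normalization (3305 genes at an unadjusted p under 0.05) or cyclic loess (3290 such genes). None of the 36 passed when all probe sets were tested together. The count was 2738 without sham replicate 1 and 157 without sham replicate 4, with all 36 among them in both. Without IUGR replicate 2 it was 43, with 21 of the 36 among them. Without IUGR replicate 4 it was 2, with none of the 36. The count was 0 without sham replicate 2, sham replicate 3, IUGR replicate 1 or IUGR replicate 3. The folds moved less than the count. The median of the 34 higher genes was 1.02 after quantile normalization and 1.03 after cyclic loess, with a median SE of the 36 of 0.18 and 0.17 (0.16 before), and all 36 stayed without overlap under both. Leaving out 1 litter at a time, Car12 lay between 2.17 and 2.74, Gnmt between 1.99 and 2.33 and Ndn between -2.30 and -1.93. The direction of the wider set depended on scaling too: of 3789 genes at an unadjusted p under 0.05, 58.9% were higher in IUGR, against 45.9% after quantile normalization, 47.6% after cyclic loess and 13.4% after median centring, which moved the median difference of all genes from 0.04 to -0.19.

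**Figure D2:**
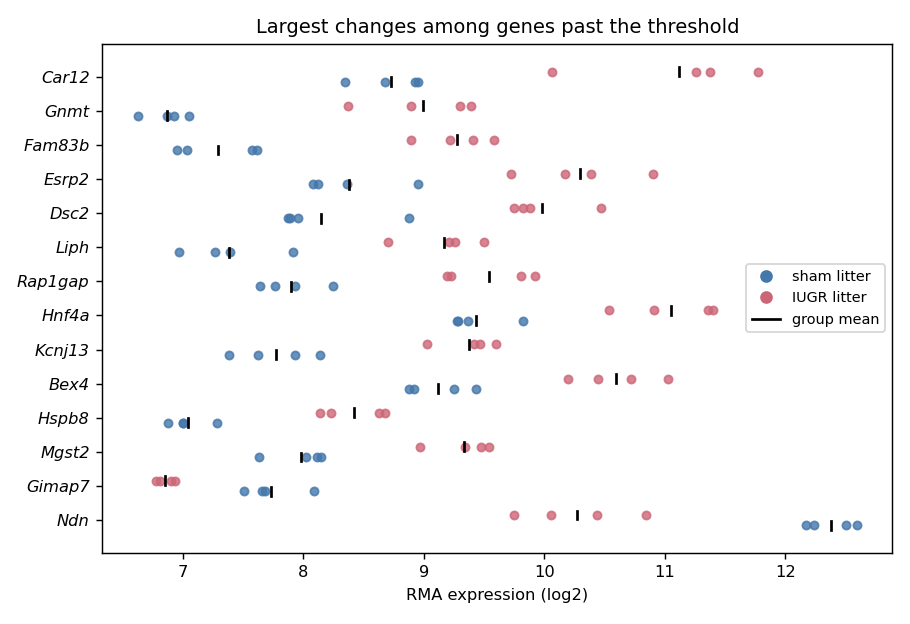
RMA expression (x axis, log2) of the genes past the threshold with the largest differences, with 1 point per litter (sham in blue, IUGR in red) and black lines for group means. Car12 was 8.73 in sham and 11.12 in IUGR litters on average, and Ndn was 12.38 and 10.27.

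Hormone genes showed no difference past the threshold. Ins1 differed by -0.20 ± 0.18, Ins2 by -0.14 ± 0.12, Gcg by 0.08 ± 0.13 and Sst by 0.10 ± 0.55 (SE, n = 4 each). Ins1, Ins2 and Gcg lay between 13.15 and 14.24, close to the highest value of each array (14.15 to 14.44), where a difference can be compressed, so these 3 genes leave open whether hormone transcripts differed. Without sham replicate 4, Ins1 differed by -0.03, Ins2 by -0.03 and Gcg by 0.20. In the list of islet hormones and granule proteins, 17 of 23 members were higher, 0 passed over all genes and 0 adjusted over the list alone. Its median difference was 0.10 (camera adjusted p = 0.990), and the test ran in the lower direction while the median and mean were positive. Chgb (0.63), Ppy (-0.53), Pyy (0.49) and Npy (-0.46) had the smallest p-values, and without sham replicate 4 Ppy was -0.24, Pyy 0.81 and Npy -0.13. The list mean was 11.85 in sham replicate 4 against 10.28 to 10.38 in the other sham litters, and the result depended on that litter: without it the list median was 0.55 (camera adjusted p = 3.2e-06, adjusted p = 0.633 with an estimated correlation). Of the genes of glucose sensing and insulin secretion, 19 of 27 were higher, with a median of 0.13 and a camera adjusted p of 0.752, and 0 members passed over all genes or adjusted over the list alone. Without sham replicate 4 that median was 0.46 (camera adjusted p = 2.5e-06, adjusted p = 0.518 with an estimated correlation), and Sst differed by 0.71 (adjusted p = 0.119). Slc25a22 differed by 0.42, Adcy8 by -0.34, Pc by 0.48 and Vamp2 by -0.28. Slc2a2, the glucose transporter of beta cells, differed by 0.82 ± 0.51 (SE), by 1.29 without sham replicate 4 and by 0.44 without sham replicate 2. Of the 157 named genes, 30 moved by over 1.5 times when 1 litter was left out, 20 of them with sham replicate 4. None of the 30 was past the threshold on all 8 arrays. That follows largely from the choice of genes, since those past the threshold lie far from 0 against their SE. Some of the 30 lay near 0, such as Vegfa (-0.01) and Gcg (0.08), where a ratio says little.

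Islet transcription factors rose as a list. Of 33 listed members 22 were measured, without Pdx1 and Mafa. All 22 were higher, by a median of 0.66 (camera adjusted p = 3.8e-06, adjusted p = 0.559 with an estimated correlation). Duct, acinar and liver lists rose on the same arrays, so the rise was not particular to endocrine genes. The median was 0.47 after quantile normalization (0.30 with sham replicate 1 also left out) and 1.04 with the liver list mean as a covariate, and the list passed in each. The list mean of sham replicate 4, 9.03, lay next to the IUGR litters (9.09 to 9.48) and above the other sham litters (8.23 to 8.41), and without it the median was 0.98. Hnf4a passed over all genes, and 9 members passed when adjusted over the list alone. Neurog3, the factor that starts endocrine differentiation, differed by 0.84 ± 0.13 (adjusted p = 0.053), Pou3f4 by 1.08 and Foxa3 by 1.52. Nkx6-1 differed by 0.21 ± 0.38. Neither Neurog3 nor Nkx6-1 passed on all 8 arrays. Without sham replicate 4 both passed, Nkx6-1 at 0.63 (adjusted p = 0.049) and Neurog3 at 0.97 (adjusted p = 0.011). Neurog3 also passed without sham replicate 1 (0.81, adjusted p = 0.015), where 2738 genes passed. In every other fit with 1 litter left out Neurog3 did not pass (limma adjusted p from 0.067 to 0.178).

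Lists of duct and acinar cell markers rose as well. Of 17 duct markers, 15 were higher, by a median of 0.84 (camera adjusted p = 3.6e-05, adjusted p = 0.559 with an estimated correlation), and this was the 1 list of 32 that passed with fry (adjusted p = 0.017). The duct median was 0.64 after quantile normalization and 0.38 with sham replicate 1 also left out, and the list passed camera in both. The keratin gene Krt8 rose by 1.07 and was the 1 member past the threshold over all genes, and 11 members, 10 higher and 1 lower, passed when adjusted over the list alone. Krt18 differed by 0.84, Prom1 by 0.63 and Muc1 by 1.58. Of 27 acinar markers, 26 were higher, by a median of 1.02 (adjusted p = 3.8e-06, adjusted p = 0.559 with an estimated correlation), with 0 past the threshold over all genes and 6 adjusted over the list alone. The acinar median was 0.31 with the liver list mean as a covariate (adjusted p = 0.012), and with array weights it was 0.35 and did not pass (adjusted p = 0.148). Zg16 differed by 2.35 (adjusted p = 0.053), Sycn by 1.69, Bhlha15 by 1.24 and Ctrl by 1.67.

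Over all arrays, transcripts of liver proteins had the largest list median. All 20 members were higher, by a median of 1.98 (camera adjusted p = 1.6e-06, adjusted p = 0.559 with an estimated correlation). None passed over all genes, and 18 passed when adjusted over the list alone. Apoa1 differed by 1.77, Rbp4 by 1.28, Vtn by 2.08 and Apoh by 2.94. The list mean was 11.27 in sham replicate 1, 9.54 in sham replicate 2, 10.68 in sham replicate 3 and 9.04 in sham replicate 4, and it was 12.07, 11.21, 12.21 and 12.68 in IUGR replicates 1 to 4. The exact permutation p of that mean was 0.057. On the 5 arrays of wider range, which hold 1 sham litter, the liver median was 0.65. It was then below the medians of the duct (1.34), acinar (1.01) and islet transcription factor lists (0.97). That sham litter, replicate 1, had the highest liver list mean of the sham litters (11.27). This fit therefore cannot tell the signal range from the choice of litter. After quantile normalization the liver median was 1.80, against 0.83 for the acinar, 0.64 for the duct and 0.47 for the islet transcription factor list. After cyclic loess the liver median was 1.78, against 0.82, 0.67 and 0.53 in that order. With the liver list mean as a covariate, 0 genes passed, with a lowest adjusted p of 0.573. All 36 genes kept their sign: the median of the 34 higher genes was 1.04 (1.19 before), while the median SE of the 36 was 0.24 (0.16 before), and the covariate took 1 residual degree of freedom. Car12 was then 1.72 ± 0.51, Gnmt 1.53 ± 0.27, Dsc2 2.35 ± 0.38, Hnf4a 1.46 ± 0.37 and Ndn -1.84 ± 0.38 (SE). With it the list medians of duct (1.10), lymphocyte (-0.26), granulocyte (-0.50) and MHC genes (-0.26) lay farther from 0. In the list of complement and acute phase genes, 10 of 22 members were higher, with a median of -0.09, a mean of 0.32 and a camera direction that was lower (adjusted p = 0.939). None of its members passed over all genes, and 4 passed when adjusted over the list alone. A2m differed by 3.10, C3 by 1.88, Cfi by 2.52 and Clu by 0.72. Over the processing alternatives their lowest differences were 0.42, 0.44, 0.17 and 0.44.

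Cholesterol synthesis genes rose as a list, with all 19 members higher by a median of 0.57 (adjusted p = 3.8e-06, adjusted p = 0.559 with an estimated correlation), 0 passing over all genes and 12 adjusted over the list alone. With the liver list mean as a covariate the median was 0.08 (adjusted p = 0.243). That mean nearly separates the groups, so the fit cannot tell liver transcripts from group. In sham replicates 1, 2 and 3 the cholesterol list mean was 10.44, 10.44 and 10.51, while the liver list mean was 11.27, 9.54 and 10.68. Both means were lowest in sham replicate 4 (9.91 and 9.04) and highest in IUGR replicate 4 (11.39 and 12.68). In IUGR replicates 1, 2 and 3 the cholesterol mean was 10.85, 10.66 and 10.80 and the liver mean 12.07, 11.21 and 12.21. Sqle differed by 0.82, Lss by 0.64, Cyp51 by 0.67 and Dhcr7 by 0.73. Hypoxia-induced genes also rose, with 28 of 36 higher by a median of 0.33 (adjusted p = 0.00040, adjusted p = 0.559 with an estimated correlation), 0 passing over all genes and 8 adjusted over the list alone. With that covariate the hypoxia median was 0.14 (adjusted p = 0.016), and on the 5 arrays of wider range 0.16 (adjusted p = 0.051). Pdk1 differed by 0.95, Ero1a by 0.53, Hk2 by 0.76 and Ndrg1 by 0.95, while Vegfa differed by -0.01 ± 0.15 (SE). Glycolysis and gluconeogenesis genes rose, 20 of 24 being higher by a median of 0.28 (adjusted p = 0.0050, adjusted p = 0.559 with an estimated correlation), with 0 passing over all genes and 2 adjusted over the list alone. With the covariate this median was 0.09 (adjusted p = 0.129). Fbp1 differed by 1.08, Pfkl by 0.59 and Tpi1 by 0.42. The hypoxia and glycolysis lists share members, among them Hk2 and Tpi1, so their rises are not separate results. The medians were 0.19 for hypoxia and 0.19 for glycolysis after quantile normalization, both still passing. Genes in groups of similar signal (means of 10.21 and 10.89) differed as a whole by 0.17 and 0.15. Part of these 2 small rises is therefore not particular to the lists.

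Genes of the mitochondrial respiratory chain rose by a small median of 0.18, with 50 of 55 higher (adjusted p = 5.1e-05, adjusted p = 0.657 with an estimated correlation). The list mean was 11.18 in sham replicate 4 against 11.60 to 11.63 in the other sham litters, and without it the median was 0.08 (adjusted p = 0.012). It did not pass with array weights (0.08, adjusted p = 0.057) or with the liver list mean as a covariate (-0.04, adjusted p = 0.704). Uqcrfs1, the Rieske subunit of complex III, rose by 1.30 and passed over all genes, and 5 members passed when adjusted over the list alone. Ndufa6 differed by 0.61, Ndufa2 by 0.45 and Ndufb3 by 0.52. Genes of mitochondrial biogenesis and replication rose, with 18 of 19 higher by 0.41 (adjusted p = 0.0020, adjusted p = 0.559 with an estimated correlation), 0 passing over all genes and 3 adjusted over the list alone. The call was lost after quantile normalization (0.22, adjusted p = 0.104), after cyclic loess (0.22, adjusted p = 0.055), without dim genes (0.38, adjusted p = 0.069), and most strongly with the liver covariate (0.04, adjusted p = 0.669) and on the 5 arrays of wider range (0.07, adjusted p = 0.537). The median was 0.19 without sham replicate 4. Twnk differed by 0.67, Ppargc1a by 1.43, Top1mt by 0.46 and Mterf1 by 0.84. Unfolded protein response genes rose, with 23 of 27 higher by 0.24 (adjusted p = 0.00083, adjusted p = 0.559 with an estimated correlation), 0 passing over all genes and 3 adjusted over the list alone. Without dim genes this list did not pass, its median being about as large (0.23, adjusted p = 0.058). Herpud1 differed by 0.83, Sel1l by 0.78, Eif2ak3 by 0.45 and Dnajc3 by 0.42. Heat shock proteins rose, with 15 of 16 higher by 0.29 (adjusted p = 0.0031, adjusted p = 0.559 with an estimated correlation). Hspb8 passed over all genes and 4 members adjusted over the list alone, Hsph1 differing by 1.13, Dnajb1 by 0.93 and Bag3 by 0.49. Heat shock proteins did not pass with the liver covariate (0.02, adjusted p = 0.095), without dim genes (0.25, adjusted p = 0.069) or with array weights (0.09, adjusted p = 0.181), and the median was 0.11 without sham replicate 4 (adjusted p = 0.012). Quantile normalization gave medians of 0.11 for the respiratory chain, 0.14 for the unfolded protein response and 0.21 for heat shock proteins, all still passing. Genes in groups of similar signal (means of 10.89 and 11.92) differed as a whole by 0.15 and 0.08. Part of these small rises is therefore not particular to the lists.

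Lists of blood, immune, vascular and stromal genes fell by camera at the preset correlation, but their list means overlapped between the groups. Exact permutation p-values of the list means were 0.229 for macrophage, 0.057 for mesenchyme, 0.171 for erythroid and 0.400 for endothelial genes. The macrophage mean was 9.66 and 9.65 in IUGR replicates 2 and 3, against 9.59, 9.66 and 9.45 in sham replicates 2 to 4. Macrophage markers were lower in 27 of 29 members, by a median of -0.54 (adjusted p = 8.6e-06, adjusted p = 0.559 with an estimated correlation), with Lyz2 differing by -0.92, Trem2 by -0.42, Fcer1g by -0.76 and Tyrobp by -0.76. Mesenchyme and matrix genes were lower in 24 of 26 by -0.45 (adjusted p = 8.6e-06, adjusted p = 0.559 with an estimated correlation), Sparc differing by -0.33, Thy1 by -0.79, Postn by -0.79 and Dpt by -0.75. Erythroid genes were lower in 18 of 18 by -0.67 (adjusted p = 2.6e-05, adjusted p = 0.559 with an estimated correlation), Hbb-b1 differing by -0.52, Ahsp by -0.65, Alas2 by -0.95 and Slc4a1 by -0.86. Endothelial markers were lower in 24 of 24 by a small -0.16 (adjusted p = 0.0087, adjusted p = 0.720 with an estimated correlation), Cd34 differing by -0.53, Ramp2 by -0.49, Plvap by -0.52 and Kdr by -0.24. The endothelial median was 0.06 with array weights, and the call was lost without sham replicate 1 (-0.12, adjusted p = 0.112), sham replicate 4 (-0.06, adjusted p = 0.319) or IUGR replicate 4 (-0.04, adjusted p = 0.214), and with the liver list mean as a covariate (0.03, adjusted p = 0.669). It was larger without sham replicate 2 (-0.29, adjusted p = 4.5e-05) and after quantile normalization (-0.32, adjusted p = 0.00018). With the covariate the mesenchyme and matrix list no longer passed and its median was near 0 (-0.02), while the macrophage median was -0.74 and the erythroid median -0.83. Without IUGR replicate 1 the erythroid median was -0.39, without IUGR replicate 4 the mesenchyme median was -0.29, and without sham replicate 1 or IUGR replicate 1 the macrophage median was -0.35 or -0.36, all still passing. In these 4 lists 0 members passed over all genes and 0 adjusted over the list alone.

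Lymphocyte markers fell, with 23 of 25 lower by -0.21 (adjusted p = 0.00051, adjusted p = 0.559 with an estimated correlation), 0 passing over all genes and 1 adjusted over the list alone. The call was lost after quantile normalization (-0.03, adjusted p = 0.332) and cyclic loess (-0.08, adjusted p = 0.094). The list mean was 7.64 in sham replicate 1 against 7.24 to 7.28 in the other sham litters, and without it the median was -0.12 (adjusted p = 0.014), and -0.14 without IUGR replicate 1. Cd27 differed by -0.49, Gzmb by -0.49, Tbx21 by -0.27 and Cd3d by -0.22. Granulocyte and mast cell markers fell, with 16 of 22 lower by -0.40 (adjusted p = 0.013, adjusted p = 0.559 with an estimated correlation) and 0 passing over all genes or adjusted over the list alone. The call was lost after quantile normalization (-0.28, adjusted p = 0.063) or median centring (-0.63, with the median of all genes at -0.19, adjusted p = 0.092), with array weights (-0.14, adjusted p = 0.106) and without sham replicate 1 (-0.21, adjusted p = 0.164) or IUGR replicate 1 (-0.28, adjusted p = 0.113). Its members moved apart, Hdc, the histidine decarboxylase gene, differing by 2.23, Ngp by -1.62, Mcpt1 by -1.72 and Csf3r by -0.73. MHC and antigen presentation genes fell, with 16 of 20 lower by -0.21 (adjusted p = 0.030, adjusted p = 0.657 with an estimated correlation). Of its members 0 passed over all genes and 1 adjusted over the list alone, and that member was higher, against the list. The list mean was 9.82 in sham replicate 1 against 9.25 to 9.32 in the other sham litters. Without that litter the list did not pass (-0.11, adjusted p = 0.402), nor without IUGR replicate 4 (-0.14, adjusted p = 0.111) or with array weights (-0.03, adjusted p = 0.723). RT1-CE5 differed by 0.36, uncertain because close copies of class I genes share probes, Ciita by -0.23, RT1-DMb by -0.60 and B2m by -0.18. Cytokines and chemokines fell by -0.08 with 31 of 47 lower (adjusted p = 0.038, adjusted p = 0.559 with an estimated correlation), with 0 passing over all genes or adjusted over the list alone. Cytokines no longer passed in 11 of 21 settings, among them quantile normalization (-0.05, adjusted p = 0.568), median centring (-0.31, adjusted p = 0.173), the liver covariate (-0.04, adjusted p = 0.547) and the fits without sham replicate 4 (-0.06, adjusted p = 0.218), IUGR replicate 3 (-0.07, adjusted p = 0.133) or IUGR replicate 4 (-0.05, adjusted p = 0.117). Without IUGR replicate 1 the median was larger (-0.14, adjusted p = 0.0045). Tgfb1 differed by -0.57, Ccl19 by -0.66, Il1a by 0.84 and Cxcl10 by -0.52. Of the cytokine genes fixed in advance, Il4 differed by -0.08 ± 0.07, Il10 by -0.01 ± 0.08, Il13 by -0.29 ± 0.13 and Ccl2 by -0.16 ± 0.31 (SE). Il4 and Il10 were near the floor, with group means of 6.02 to 6.36, and the genes in groups of similar signal (means of 5.71 and 6.23) differed as a whole by -0.17 and -0.16.

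**Figure D3:**
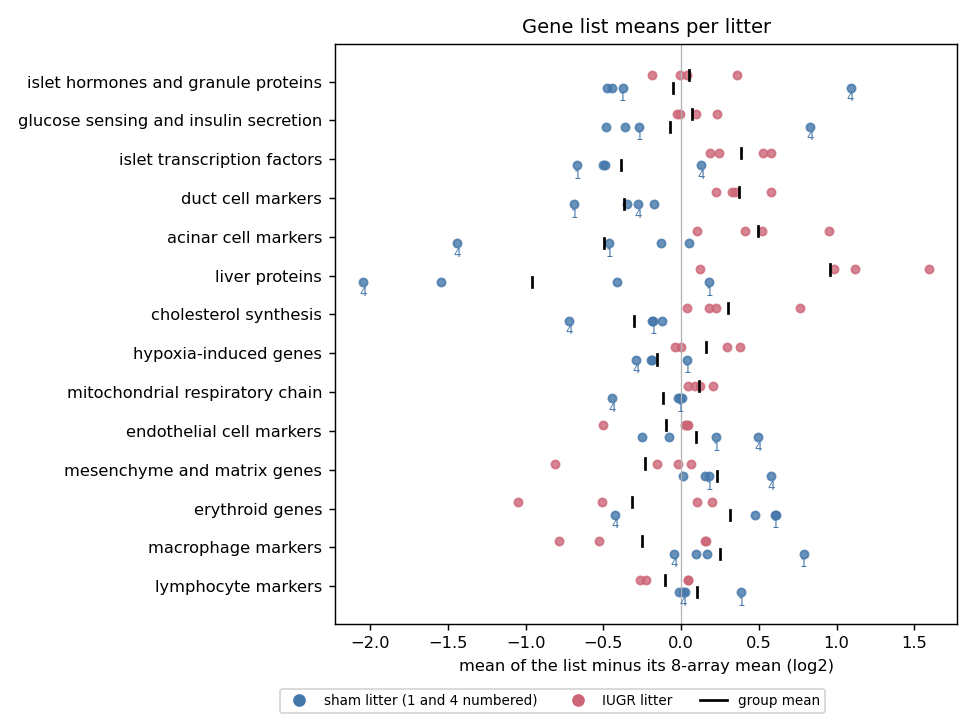
Mean of each of 14 gene lists per litter, minus its 8-array mean (x axis, log2), with sham litters in blue, IUGR litters in red, black lines for group means, and sham replicates 1 and 4 numbered. The 2 endocrine lists at the top hold sham replicate 4 far from the other sham litters, and the liver list spans the widest range.

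The remaining lists did not pass. Th2 cytokine receptors and response had 16 of 24 lower by -0.19 (adjusted p = 0.050), with Socs1 differing by 0.27, Ccr4 by -0.28 and Arg1 by 0.87. Antioxidant defence had 25 of 34 higher by 0.16 (adjusted p = 0.060), Nfe2l2 differing by 0.58, Gsr by 0.68, Keap1 by 0.41 and Prdx4 by 0.47. Cell cycle genes had 33 of 42 higher by 0.14 (adjusted p = 0.173), with Ccnd2 at 0.41, Kif23 at 0.30, Cdt1 at 0.41 and Birc5 at 0.40. DNA methylation and histone modifiers had 15 of 18 higher by 0.10 (adjusted p = 0.152), with Kat2b at 0.37, Suv39h1 at 0.28, Sin3a at 0.24 and Ehmt2 at 0.23. IGF and insulin signalling had 15 of 27 higher by 0.09 (adjusted p = 0.990), with H19 at 0.70, Igfbp2 at 1.13, Igfbp6 at -1.12, Ghr at 0.39 and Igf2 at 0.12 ± 0.11 (SE). Targets of p53 and apoptosis genes had 17 of 26 higher by 0.10 (adjusted p = 0.857), with Cdkn1a at 0.69, Bcl2l11 at 0.56 and Mdm2 at 0.34. Glucocorticoid-induced genes had 13 of 26 higher by 0.01 (adjusted p = 0.990), with Pdk4 at 0.92, Mt2A at 0.43 and Nr3c1 at 0.26. Neural and Schwann cell markers had 9 of 16 higher by 0.08 (adjusted p = 0.909), with Erbb3 at 1.12, Sox2 at 0.25, Gfra3 at 0.47 (0.23 without sham replicate 2) and S100b at -0.53 (-0.20 without sham replicate 3). Interferon-stimulated genes had 16 of 32 higher, with a median of 0.04 but a mean of -0.03 (adjusted p = 0.990), and Isg20 differed by 0.81, Isg15 by -0.35, Ifih1 by 0.61 and Rig1 by 0.46. Immediate early genes had 16 of 30 lower by -0.08 (adjusted p = 0.323), with Myc at 0.41, Dusp1 at -0.26, Fos at -0.26 and Klf2 at -0.59, where without sham replicate 4 Myc was 0.26, Fos -0.13 and Klf2 -0.19. In these 10 lists 0 members passed over all genes. Adjusted over the list alone, 1 higher member passed in antioxidant defence, 1 in the neural list and 1 in the interferon list. In the p53 list and in the glucocorticoid list the 1 member that passed was lower, and in both it was Cdkn1c (-0.74). In the IGF list 4 members passed, 3 higher and 1 lower, and 0 passed in the other lists of this group.

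Across the 32 lists, 19 passed camera at the preset correlation, 11 higher and 8 lower. With an estimated correlation 0 passed and with fry 1. With the exact permutation test 0 passed after adjustment, where the smallest adjusted p was 0.091. In that test 10 lists had an unadjusted p under 0.05, and all 10 were higher in IUGR. The 8 lists that camera called lower had unadjusted exact permutation p-values from 0.057 (mesenchyme) to 0.657 (cytokines).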

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

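The tests of signal range, of sham replicate 1 and of the share of stroma were chosen after the results were seen. Those of intestinal markers, of hepatocyte markers and of other splits of the arrays were written before. A sample far from the other 3 of its group was found in 34 of 380 groups of values, where chance gives about 19, and 17 of the 34 were in sham replicate 4.

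Sham replicate 4 lay above the other sham litters in the list means of islet hormones (11.85 against 10.28 to 10.38) and of glucose sensing (9.28 against 7.97 to 8.19), and in Ins2 (14.24), Sst (12.83), Pyy (13.59), Npy (13.05), Nkx6-1 (9.76), Neurog3 (10.31), Cd34 (12.58) and Dsc2 (8.88). It lay below them in the list means of erythroid genes (10.38), cell cycle genes (10.39), the respiratory chain (11.18) and cholesterol synthesis (9.91), and in Pdk1 (9.49), Ndufa6 (9.74) and Hsph1 (9.14). Sham replicate 1 lay apart in the list means of lymphocyte markers (7.64), MHC and antigen presentation (9.82) and p53 targets (9.57), and in Gzmb (7.62) and Twnk (8.66). Apobr in sham replicate 2 was 7.57 and S100b in sham replicate 3 was 8.32. IUGR replicate 4 lay apart in the list means of endothelial markers (10.002) and mitochondrial biogenesis (9.63), and in Il4 (6.34), Kdr (10.75), Postn (10.62), Igfbp2 (10.68) and Dhcr7 (11.59). Isg15 in IUGR replicate 2 was 6.09, Ccnd2 in IUGR replicate 3 was 12.58 and Bag3 in IUGR replicate 1 was 10.01. Outside the named genes, 3 probe sets without a gene passed the threshold when all probe sets were tested.

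The first pattern was that genes were more often higher than lower in IUGR, with sham replicates 2 to 4 having a narrower signal range. Among genes at an unadjusted p under 0.05, the share that was higher went from 58.9% to 45.9% after quantile normalization. That scaling sets the median difference of all genes near 0 (-0.0038), which largely imposes such a balance, so whether the narrower range caused the excess cannot be told apart. Cyclic loess removes differences that genes of similar signal share, and between the groups these reached only 0.22 (at a mean signal of 9.03). It could therefore not have removed rises with a median of 1.19, and the 34 genes were picked as higher on these same arrays. The test thus does not decide how far the narrower range accounts for the size of the 34 rises. After cyclic loess their median was 1.03 (1.19 before), their lower quartile was 0.90 and 34 of 34 were positive. None passed then, the lowest adjusted p being 0.051 (limma). Only 1 of the 35 splits of the 8 arrays, the real one, gave as many as 36 genes, the highest other giving 4. That is the smallest share that 35 splits can give, and the splits used the deposited values alone. Chance is therefore not excluded for that count. For the lists the splits gave no evidence against chance, since 8 of the 35 splits gave as many as 19 lists and the highest other gave 23.

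The second pattern was that sham replicate 1 correlated best with an IUGR array (0.985 against 0.982 with a sham array). A mislabelled IUGR array stayed open after 2 tests with differing answers. On the islet transcription factor list, picked after it was seen to separate the groups and so deciding nothing, sham replicate 1 (8.23) lay 0.853 below the lowest IUGR litter (9.09). On the 200 genes that best separated the other 7 arrays after quantile normalization, a second test written after that one, its position from sham (0) to IUGR (1) was 0.886, within the 0.39 to 1.09 of IUGR arrays held out in the same way, but sham replicate 4 at 0.44 was within them too, so that test separates the groups poorly. Whether signal range is the cause cannot be told apart, because the margin over the sham arrays was 3.97e-06 after cyclic loess (0.0031 before).

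The third pattern was that liver, acinar and duct transcripts were higher in IUGR. More liver tissue in those preparations is a candidate explanation for the liver part: 24 hepatocyte markers outside the lists differed by a median of 1.83, 22 of them higher, and their mean per array followed the liver list (r = 0.978, exact permutation p = 2.5e-05, rho = 1, exact permutation p = 5e-05, each the smallest that 40320 arrangements can give, 1 relation computed, r = 0.941 without the 2 farthest arrays), while their mean differed by 1.61 with an exact permutation p of 0.057. Alb was 13.92, 12.95, 13.78 and 11.69 in sham replicates 1 to 4 and 13.81 to 13.98 in IUGR, and the labels name no sort that would remove liver cells. Other values ran the other way. Fetal liver also makes red cells, yet erythroid genes were lower in 18 of 18, with Hbb-b1 at 13.72 to 13.86 in sham and 12.99 to 13.58 in IUGR. That does not exclude liver tissue, since red cells also come with blood. Cps1, made by liver and intestine and itself a member of the liver list, was 7.75, 10.90, 6.63 and 10.16 in sham replicates 1 to 4. It was thus higher in the 2 with the lower liver list. In IUGR it was 12.61, 10.56, 10.55 and 11.26. The mean of the 17 intestinal markers was 7.52, 8.96, 7.77 and 9.10 in sham and 10.40, 8.91, 8.92 and 8.32 in IUGR. It was higher in the same 2 sham litters, so Cps1 does not decide against liver tissue. Most Alb values and all Hbb-b1 values lay near the highest value of each array, where a difference can be compressed. For the epithelial part, intestinal epithelium and a lower share of stroma and blood cannot be told apart from other causes: 17 intestinal markers differed by 0.80 ± 0.60 (SE, exact permutation p = 0.286), and duct and acinar minus endocrine lists by 0.26 ± 0.19 without sham replicate 4 and by 0.74 ± 0.50 with it, too wide to decide against a bound of 0.3 set after the values were seen.

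The response of islets to growth restriction itself stayed open for all 3 patterns and was not tested apart from these.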

How the results depend on the processing

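Cyclic loess, the combined array choices, the 5 arrays of wider range, the covariates and the permutation test of list means were chosen after the data were examined, and all other alternatives before. The count of 36 genes (34 higher, 2 lower) moved with most choices, while camera at the preset correlation passed 14 to 23 lists under every alternative that kept that test. The number of lists is no sign of stability, since wrong splits of the 8 arrays gave 3 to 23 lists with the same test. The count was 30 with a trended robust prior, 35 with the mean of a gene's probe sets, and 59 (57 higher) without dim genes. It was 0 after quantile normalization (lowest adjusted p 0.096) and after cyclic loess (0.051), and 1 after median centring (0 higher, 1 lower). The lowest adjusted p over the alternatives for genes ranged from 0.00054 to 0.573. With all probe sets it was 3, all without a named gene. Array weights gave 6358 genes (3825 higher, 2533 lower), with a weight of 7.82 on sham replicate 3 and 0.20 on sham replicate 4. It was 2795 (1526 higher, 1269 lower) without sham replicates 1 and 4 together, 805 (237 higher, 568 lower) after quantile normalization with sham replicate 1 left out, 0 on the 5 arrays of wider range, where the lone sham litter was assumed to vary like the IUGR litters, 0 with the liver list mean as a covariate (all 36 kept their sign, the median of the 34 being 1.04 and the median SE 0.24 in place of 0.16), and 1087 (978 higher, 109 lower) with the hormone list mean as a covariate. Leaving out 1 litter at a time gave 0 to 2738 genes, 0 to 1347 higher and 0 to 1391 lower, and 16 to 23 lists. Without sham replicate 1 it was 2738, and the remaining sham arrays then all had the narrower signal range. Of the 19 lists, 5 kept the call in all 21 settings with that test (liver proteins in all 20): islet transcription factors, duct, erythroid, macrophage and liver. It was lost in 1 setting by hypoxia (5 arrays), mesenchyme (-0.02), cholesterol synthesis (0.08) and glycolysis (0.09) (liver covariate) and acinar markers (array weights, 0.35, adjusted p = 0.148), in 2 by the unfolded protein response, in 3 by lymphocyte markers, in 3 by the respiratory chain, in 4 by MHC, in 5 by heat shock, in 6 by endothelial markers and mitochondrial biogenesis, in 7 by granulocyte markers and in 11 by cytokines. The hormone list passed in 5 settings, 1 of them without sham replicate 4. The 19 lists became 0 with an estimated correlation, 1 with fry and 0 with the exact permutation test. The replicate numbers did not pair the litters: the correlations of same-numbered deviations were -0.43, 0.095, -0.12 and -0.13, no litter number was its own best match, and the fit with the replicate number as a block gave 0 genes (0 higher, 0 lower). The cause of these changes was not tested, except that fewer genes or arrays were tested where they were left out.

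Each list is given here by its median difference. After quantile normalization the opposite sign was taken by the median of the lists islet hormones -0.027, glucose sensing -0.012, p53 targets -0.078, IGF -0.10, glucocorticoid -0.088, DNA methylation -0.030, and by the genes Sst -0.027, Nkx6-1 -0.031, Il4 0.11, Il10 0.20, Cd3d 0.00046, Ehmt2 -0.0022. After median centring, which moved every gene by a constant per array and the median of all genes to -0.19, the opposite sign was taken by the median of the lists islet hormones -0.13, glucose sensing -0.10, neural -0.15, interferon -0.20, cell cycle -0.10, respiratory chain -0.048 (still passing as higher than other genes, adjusted p = 0.0058), antioxidant defence -0.069, p53 targets -0.13, IGF -0.14, glucocorticoid -0.22, DNA methylation -0.13, and by the genes Gcg -0.15, Sst -0.13, Nkx6-1 -0.024, Igf2 -0.11, Ehmt2 -0.0034. Without dim genes the opposite sign was taken by the median of the lists interferon -0.12, complement 0.16. With array weights the opposite sign was taken by the median of the lists endothelial 0.062, neural -0.00060, Th2 0.026, and by the genes Vegfa 0.20, Il10 0.044, Ccl2 0.31. After cyclic loess the opposite sign was taken by the median of the lists islet hormones -0.0030, p53 targets -0.060, IGF -0.092, glucocorticoid -0.081, DNA methylation -0.023, and by the genes Sst -0.047, Il4 0.049, Il10 0.16. Without sham replicates 1 and 4 together the opposite sign was taken by the median of the lists endothelial 0.057, immediate early 0.053, and by the genes Vegfa 0.13, Il10 0.020. On the 5 arrays of wider range the opposite sign was taken by the median of the lists cytokines 0.027, interferon -0.10, cell cycle -0.11, p53 targets -0.15, IGF -0.051, glucocorticoid -0.065, immediate early 0.12, DNA methylation -0.054, and by the genes Il13 0.071, Ccl2 0.13, Mdm2 -0.012, Myc -0.019, Ehmt2 -0.030. After quantile normalization with sham replicate 1 left out the opposite sign was taken by the median of the lists islet hormones -0.14, glucose sensing -0.087, neural -0.041, lymphocyte 0.024, p53 targets -0.070, IGF -0.16, glucocorticoid -0.12, DNA methylation -0.020, and by the genes Sst -0.26, Nkx6-1 -0.20, Il4 0.17, Il10 0.30, Cd3d 0.13, Socs1 -0.026, Sin3a -0.0068. With the liver list mean as a covariate the opposite sign was taken by the median of the lists endothelial 0.030, interferon -0.060, cell cycle -0.22, respiratory chain -0.036, antioxidant defence -0.0046, p53 targets -0.071, immediate early 0.18, and by the genes Ins1 0.13, Ins2 0.11, Ccl2 0.73, Ppy 0.11, Npy 0.35, Pc -0.17, Vamp2 0.022, Cd34 0.032, Hdc -0.082, Myc -0.16, Klf2 0.0060. Leaving out 1 litter at a time, these values changed sign within their range: the neural list -0.069 to 0.13, islet hormones -0.026 to 0.55, IGF -0.051 to 0.13, glucocorticoid -0.059 to 0.093, interferon -0.049 to 0.088, cell cycle -0.040 to 0.22, immediate early -0.13 to 0.063, Gcg -0.0015 to 0.20, Sst -0.15 to 0.71, Vegfa -0.13 to 0.073, Il10 -0.053 to 0.016 and Ccl2 -0.35 to 0.045. The liver and hormone lists and their members were not evaluated with their own mean as a covariate, since that fixes the outcome. Over the alternatives other than single litters left out, named genes kept sign and side of the threshold in 1633 comparisons, lost the call in 96, gained it in 242 and changed sign in 42. Lists kept both in 344, lost the call in 92, gained it in 22 and changed sign in 52. The sign changes of genes and lists include those under median centring, which moved all genes of an array alike.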

Other observations

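Beyond the named genes, other genes past the threshold were looked at after their values were seen. The desmosomal gene Perp rose by 1.21, the plakophilin gene Pkp2 by 1.14, the tight junction gene Tjp3 by 1.04 and the transcription factor Ovol1 by 1.01. The bile acid receptor gene Nr1h4 rose by 0.96, the receptor genes Lgr4 by 0.85 and Gfra1 by 0.88, Ggt1 by 1.17 and the deacetylase gene Hdac11 by 1.07. With the liver list mean as a covariate none of the 36 passed, while all kept their sign: Perp was then 1.53 ± 0.19, Pkp2 1.31 ± 0.28, Tjp3 0.98 ± 0.24 and Ovol1 1.03 ± 0.25 (SE), against SEs of 0.14, 0.17, 0.14 and 0.15 before.

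Ndn, Cdkn1c and H19, which differed by -2.11, -0.74 and 0.70, are imprinted genes, and the hypothesis was tested that imprinted genes were lower as a group. The gene set was written before its values were seen, while the bound on the lower quartile and the removal of members that a list already held were set after. The other 24 imprinted genes had a median difference of 0.06, with quartiles of -0.14 and 0.33, 13 of them higher and 11 lower (camera p = 0.967, p = 0.970 with an estimated correlation), and 7 had an unadjusted p under 0.05. Since the members went both ways, the test gave no evidence for the hypothesis and did not exclude it. Kcnq1 differed by 1.18, Slc22a18 by 1.05 and Phlda2 by 0.88, and Plagl1 by -0.40 and Mest by -0.34, none past the threshold over all genes.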
